A study of Mus musculus with 24 samples.

How the data were processed

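Amplicon sequencing of integrated lentiviral barcodes was analysed in 24 samples of mouse genomic DNA, 8 sorted populations from each of 3 recipient mice. Per the labels' protocols, stem cells from bone marrow of C57BL/6 mice were infected 5 days after plating and sorted 4 days after infection. Recipients aged 5 weeks received them after whole-body irradiation with 9 Gy, together with rescue cells, and blood, heart and kidney were taken 2 months later. Barcodes were amplified in 18 PCR cycles, followed by 9 to 11 cycles that added sequencing indexes. The labels do not say how many cells were sorted or by which markers M1 and M2 macrophages were defined.

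The deposited files hold, per the file headers, 1 sample each, with a read count for every distinct barcode sequence of 52 bases. The counts are whole numbers and are not normalised. How the authors trimmed, filtered and counted reads is not given in the sources used here. All files together list 327974 distinct sequences, of which each sample holds 10660 to 55216, many with 1 read. Between 82.2% and 96.4% of a sample's reads follow an alternating pattern in which G or C and A or T take turns. The barcodes are synthetic, so they have no position in a genome, and the sites of integration were not analysed here.

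Samples were grouped by the cell type and mouse number in their titles. The same number in different populations was taken as the same animal. This was checked by the overlap of barcodes, 0.410 on average within a number and 0.0136 between numbers, so the numbers pair the samples. No 2 files agreed within sampling noise: the smallest chi-square over its degrees of freedom among the 276 pairs of samples was 83.4. The labels give no batch. Samples held 6808221 to 15745444 reads. Many permutation tests exchanged labels among several populations of the same mouse. Their p-values therefore reflect the spread between populations as well as between these 3 animals. Permutations of 3 samples against 3 could not go below p = 0.1, and sign flips over 3 mice not below p = 0.25.

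Counts were divided by the sample's total to give shares. A barcode counted as present at 0.01% of reads, which corresponds to 681 to 1575 reads. The effective number of barcodes was the exponential of the Shannon entropy. Similarity of 2 samples was the sum over barcodes of the smaller share (the Bray-Curtis similarity). Tests on these measures permuted labels, exactly where the number of assignments allowed it and otherwise 100000 times with a fixed seed (Python 3.11.15, numpy 2.4.6, scipy 1.17.1), and their p-values were adjusted over 13 tests by the Benjamini-Hochberg method. Diversity was tested on a log10 scale. Eta squared is the between-population share of the sum of squares.

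Single barcodes were tested with edgeR 4.0.16 (R 4.3.3), using TMM normalisation, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Comparisons of groups of populations used counts summed per mouse. On simulated counts of the Ccr2hi and Ccr2lo samples with 200 barcodes changed 4-fold, the test recovered 100% of them among 1620 barcodes when every mouse had the same level, with 3 false calls. With barcodes at the level of each mouse it recovered 0% of them among 1508 without a block, and 89.5% with the mouse as a block, with 6 false calls among 185. A count of 0 without the block therefore says little on barcodes of single mice, and single barcodes were also compared within each mouse by fold, without a test. The simulated counts had a dispersion set to 0.05, not estimated from these data. How many changes the block would recover in the real counts is therefore not known. The other measures were tested on 400 simulated barcodes: merging removed 100% of planted errors, the effective number after merging was 175 against a true 176, and 4% of 200 data sets without an effect gave p under 0.05.

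Barcodes were named by a rule fixed before the data were examined: in each mouse the 5 with the highest mean share over its populations, in each edgeR comparison up to 10 with the largest log2 fold change among those called, and in each mouse the most myeloid and most lymphoid by the log2 ratio of mean shares with 0.01% added, among barcodes with a mean of 0.1% over the blood populations. Other barcodes named in the closing section were chosen after their values were seen.

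Alternatives set before the data were examined were thinning to 6808221 reads, merging barcodes 1 mismatch from a barcode at least 10 times as abundant in the sample, removing barcodes under 10 reads, removing barcodes at least 100 times as abundant in another mouse, leaving out each mouse, permuting within mice, other thresholds for presence, the inverse Simpson index, and the Morisita-Horn, Jaccard and Spearman measures of similarity. For single barcodes they were the mouse as a block, total counts without TMM, DESeq2 1.42.0 (size factors from positive counts), other filters, merging, leaving out each mouse, and samples entered singly. Restricting to barcodes of the alternating pattern and leaving out renal M1 macrophages, or their pair with M2 macrophages in the test by class, were added after seeing the data. Merging moved 0.602% to 0.746% of a sample's reads, and removal of other mice's barcodes took 0.328% to 1.44%.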

Results

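The data were read counts of DNA barcodes in blood cells and tissue macrophages of 3 mice. Cultured haematopoietic stem cells had each received a lentivirus carrying a random barcode, and their progeny in irradiated recipients carried the same barcode, so that populations descended from one founder cell share its sequence. From each mouse 8 populations had been sorted 2 months after transplantation: monocytes, neutrophils, B cells and T cells from blood, macrophages with high or low Ccr2 from the heart, and macrophages named M1 and M2 from the kidney. Ccr2 is the chemokine receptor through which monocytes leave the bone marrow. Each population had 3 samples, 1 per mouse, which gave 24 samples. Samples held between 6808221 reads, in neutrophils of mouse 1, and 15745444 reads, in renal M2 macrophages of mouse 2. At these depths the 95% Wilson interval of the most abundant barcode of a sample was 0.0139 to 0.0470 percentage points wide, and a count of 0 allowed a share of up to 4.41e-05% in the shallowest sample. The reads came from PCR without molecular identifiers, so these limits cover counting error only. A share of reads is a share of amplified barcode copies, not of cells. Cells without a barcode give no reads, so the data cover only the barcoded part of each population, whose size was not measured here.

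Cardiac Ccr2hi, cardiac Ccr2lo and renal M2 macrophages held many barcodes, and blood cells and renal M1 macrophages held few. Counting barcodes with at least 0.01% of a sample's reads, there were 1072 ± 199 in Ccr2hi, 1140 ± 201 in Ccr2lo and 1142 ± 232 in M2 macrophages (SD, n = 3 each). Renal M1 macrophages had 147 ± 69.9, monocytes 170 ± 51.3, neutrophils 128 ± 24.8 and T cells 123 ± 29.0, and B cells lay between with 379 ± 90.2 (SD, n = 3 each). The effective number of barcodes, the exponential of the Shannon entropy of the shares, weights each barcode by its abundance. It was 511 ± 245 in Ccr2hi, 621 ± 242 in Ccr2lo and 567 ± 194 in M2 macrophages, but 25.7 ± 7.10 in M1 macrophages, 32.1 ± 9.75 in monocytes, 27.2 ± 4.51 in neutrophils, 50.2 ± 25.9 in T cells and 111 ± 30.4 in B cells (SD, n = 3 each). Of the variance of the log10 values, the populations accounted for a share (eta squared) of 0.954 for the number of barcodes and 0.948 for the effective number. In permutation tests of the population labels each gave p = 1e-05, the smallest that 100000 permutations can give (Benjamini-Hochberg adjusted p = 4.33e-05 over 13 tests).

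**Figure D1:**
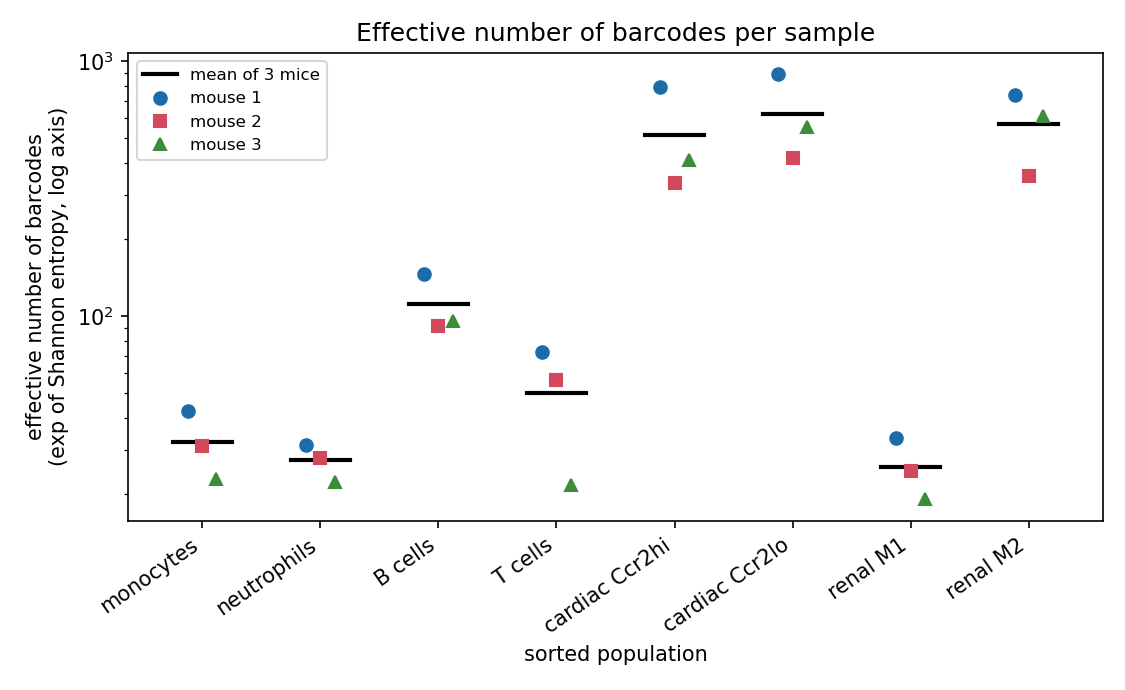
Effective number of barcodes (log axis) in each of the 24 samples, by sorted population, with 1 point per mouse and a line at the mean of 3 mice. The 9 samples of cardiac Ccr2hi, cardiac Ccr2lo and renal M2 macrophages lie between 333 and 889, above the other 15, which lie between 19.1 and 146.

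A few barcodes took most of the reads of monocytes, neutrophils and renal M1 macrophages. The most abundant barcode held 13.1% ± 4.40 of monocyte, 13.0% ± 2.44 of neutrophil and 15.1% ± 5.10 of M1 macrophage reads, against 3.69% ± 2.07 in Ccr2hi, 2.57% ± 1.51 in Ccr2lo and 4.79% ± 2.71 in M2 macrophages (SD, n = 3 each). The 10 most abundant barcodes together held 67.8% ± 6.82 of monocyte, 70.7% ± 3.69 of neutrophil and 72.5% ± 7.27 of M1 reads, 40.9% ± 4.89 of B cell and 51.99% ± 20.6 of T cell reads, and 15.4% ± 4.43 of Ccr2lo reads (SD, n = 3 each). T cells varied most between mice, from 37.8% in mouse 1 to 75.6% in mouse 3. Populations differed in the share of the most abundant barcode (eta squared 0.740, permutation p = 0.00111, adjusted p = 0.0024) and of the 10 most abundant (eta squared 0.907, permutation p = 2e-05, adjusted p = 6.5e-05).

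Tissue macrophages as a whole held more barcodes than blood cells. Their effective number was 5.54-fold that of the 12 blood samples (ratio of geometric means, two-sided permutation p = 0.00196, adjusted p = 0.00364), and 11.9-fold with renal M1 macrophages left out, an alternative added after the values were seen. In blood, monocytes and neutrophils had 0.415 times the effective number of B and T cells (6 samples against 6, exact permutation p = 0.0195, two-sided, adjusted p = 0.0281). B cells had 2.98 to 4.17 times the effective number of monocytes in the 3 mice, but T cells only 0.948 to 1.82 times, and in mouse 3 T cells (21.8) lay below monocytes (23.0). The call was lost without mouse 1 or without mouse 2, each with exact permutation p = 0.143. Cardiac macrophages had 4.55-fold the effective number of renal macrophages, which did not pass the threshold (exact permutation p = 0.0952, two-sided, adjusted p = 0.108) and fell to 0.978-fold without renal M1 macrophages. Renal M1 macrophages had 0.0463 times the effective number of M2 macrophages, and each of the 3 M1 samples lay below each M2 sample (exact permutation p = 0.1, the smallest possible with 3 against 3). The Ccr2hi and Ccr2lo values overlapped, with a ratio of 0.806 (exact permutation p = 0.5), although Ccr2lo macrophages had the higher effective number in each mouse, by 1.12 to 1.35 times.

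Populations of one mouse shared barcodes, and populations of different mice shared few. Overlap was measured as the sum over barcodes of the smaller of the 2 shares of reads, which is 0 for separate and 1 for identical repertoires. It averaged 0.410 over the 84 pairs of populations from the same mouse and 0.0136 over the 168 pairs of different populations from different mice. The difference of 0.396 had a one-sided permutation p of 1e-05, the smallest possible (adjusted p = 4.33e-05). Of 154 barcodes that reached 1% in any sample, 0 did so in more than 1 mouse. At 0.1% it was 24 of 1037 barcodes, and at 0.01% it was 291 of 4344, 27 of them in all 3 mice.

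**Figure D2:**
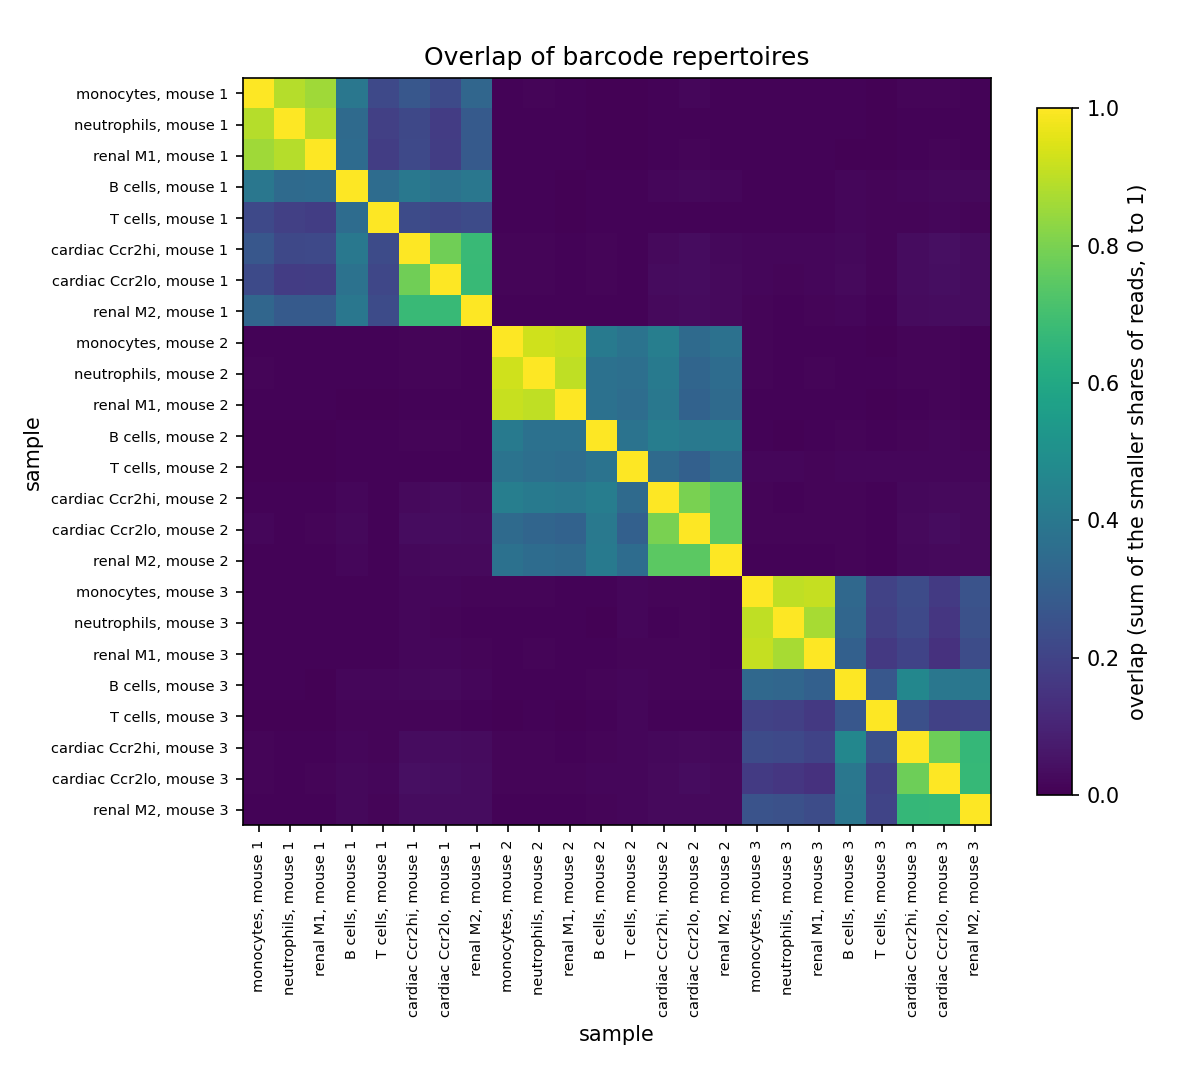
Overlap of barcode repertoires (colour, 0 to 1) between all pairs of the 24 samples, ordered by mouse and population. The 3 blocks on the diagonal are the mice, and within each the bright square of monocytes, neutrophils and renal M1 macrophages stands apart from that of cardiac and renal M2 macrophages, while overlap of different populations between mice does not exceed 0.0392.

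Within a mouse the populations fell into a myeloid group that included renal M1 macrophages and a second group of cardiac and renal M2 macrophages. Monocytes and neutrophils overlapped by 0.907 ± 0.0203, monocytes and renal M1 macrophages by 0.895 ± 0.0340, and neutrophils and M1 macrophages by 0.888 ± 0.0171 (SD, n = 3 mice each). Ccr2hi and Ccr2lo macrophages overlapped by 0.787 ± 0.0106, and renal M2 macrophages overlapped with them by 0.698 ± 0.0443 and 0.698 ± 0.0439, although they came from another organ. M1 and M2 macrophages of the same kidneys overlapped by only 0.286 ± 0.0561, and B and T cells by 0.336 ± 0.0559 (SD, n = 3 each). Pairs of one class, as grouped before the data were examined (monocytes with neutrophils, B with T cells, Ccr2hi with Ccr2lo, M1 with M2), averaged 0.579 and the other pairs of a mouse 0.382. The difference of 0.197 had a one-sided permutation p of 0.00097 (adjusted p = 0.0024). It came from monocytes with neutrophils (0.907) and Ccr2hi with Ccr2lo (0.787). M1 with M2 (0.286) and B with T cells (0.336) lay below the mean of the other pairs.

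Macrophage subsets differed in how far their barcodes matched those of circulating monocytes. The overlap with monocytes of the same mouse was 0.895 ± 0.0340 in renal M1, 0.320 ± 0.0583 in renal M2, 0.310 ± 0.106 in cardiac Ccr2hi and 0.246 ± 0.0894 in cardiac Ccr2lo macrophages (SD, n = 3 each). Ccr2hi exceeded Ccr2lo macrophages in 3 of 3 mice, by 0.0635 ± 0.0198, and so did M2 macrophages, by 0.0735 ± 0.0390 (SD, n = 3, exact sign-flip permutation p = 0.25 each, the smallest possible with 3 mice). The 4 subsets differed (eta squared 0.946, permutation p = 0.00994, adjusted p = 0.0162). The call was lost with Spearman correlation in place of overlap (eta squared 0.0624, permutation p = 0.852) and without mouse 1 or mouse 3 (permutation p = 0.106 and 0.105). Without renal M1 macrophages the test of the remaining 3 subsets did not pass the threshold (eta squared 0.174, permutation p = 0.554, and 0.167 with permutation within mice, both added after the values were seen). Barcodes at 0.01% or more in any blood population held 98.0% ± 0.710 of the M1 reads, but 66.0% ± 6.57 of the Ccr2hi, 61.6% ± 5.25 of the Ccr2lo and 60.1% ± 6.86 of the M2 reads (SD, n = 3 each).

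**Figure D3:**
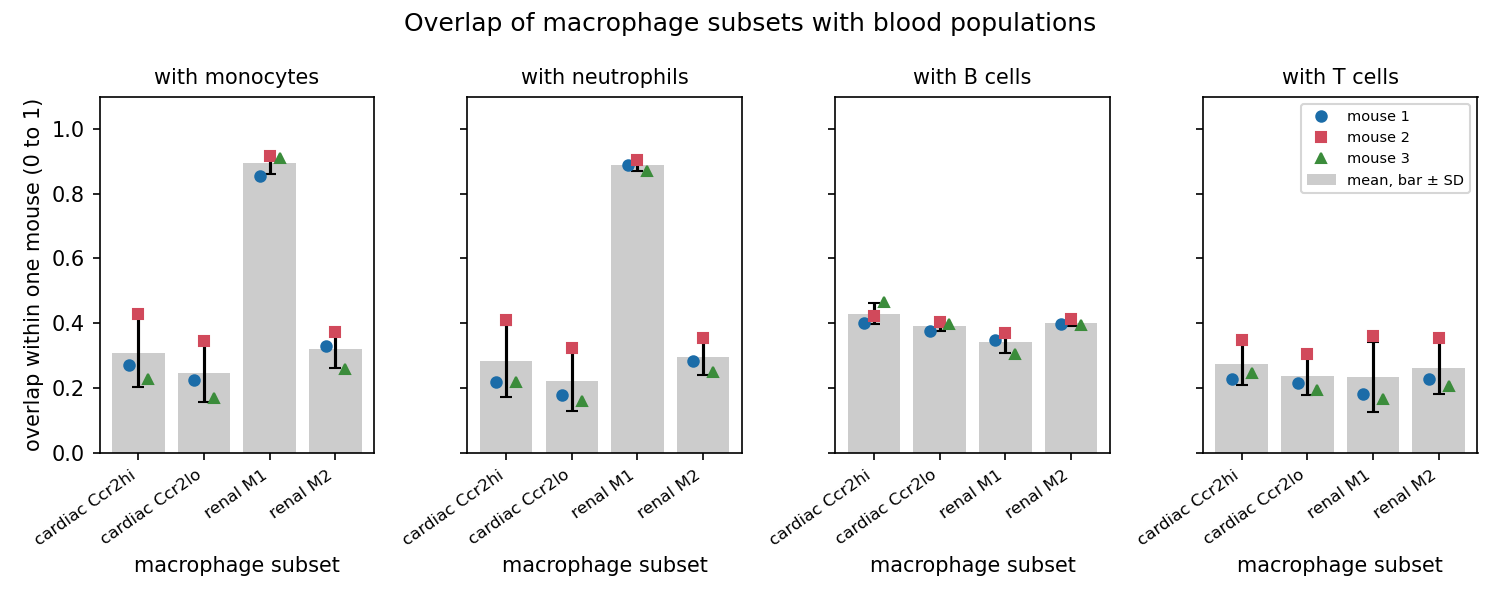
Overlap (0 to 1) of the 4 macrophage subsets with each blood population of the same mouse, with grey bars at the mean of 3 mice, error bars of 1 SD and 1 point per mouse. Renal M1 macrophages reach 0.895 with monocytes and 0.888 with neutrophils, while the other subsets stay below 0.5 with every blood population.

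Macrophages as a whole overlapped more with blood myeloid than with blood lymphoid cells, by 0.110 (two-sided permutation p = 0.029, adjusted p = 0.0378). The difference was 0.603 ± 0.0552 in renal M1 macrophages and below 0 on average in the other subsets, at -0.0549 ± 0.0845 in Ccr2hi, -0.0818 ± 0.0566 in Ccr2lo and -0.0253 ± 0.01998 in M2 macrophages (SD, n = 3 each). With M1 macrophages left out it was -0.0540 (permutation p = 0.317). The call was also lost without mouse 1, 2 or 3 (permutation p = 0.111, 0.166 and 0.0556), with the Morisita-Horn index (0.139, permutation p = 0.0755) and with barcodes of the alternating pattern only (0.111, permutation p = 0.0569, added after the values were seen), and the direction turned with the Jaccard index (-0.0111, permutation p = 0.742). With Spearman correlation in place of overlap the call was kept (0.150, permutation p = 0.00968). B cells were the blood population nearest to cardiac macrophages on average, with an overlap of 0.429 ± 0.0325 for Ccr2hi and 0.392 ± 0.0144 for Ccr2lo (SD, n = 3 each). They also had the highest effective number in blood (111), and overlap depends in part on how evenly reads are spread.

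Barcodes were also classed by where they occurred. In the 3 mice 416, 303 and 345 barcodes reached 0.1% in at least 1 population. Of these, 14.7% ± 2.73 were found at 0.01% or more in all 8 populations, 32.6% ± 2.33 in tissue macrophages only, 23.9% ± 4.10 in blood lymphoid but not blood myeloid cells, and 2.88% ± 0.657 in blood myeloid but not lymphoid cells (SD, n = 3 each). Barcodes found in both blood myeloid and blood lymphoid cells but not in tissue macrophages numbered 2 in mouse 1 and 0 in mice 2 and 3. The classes of a single blood lineage were not divided by presence in tissue, so barcodes of blood alone were not counted in full. The barcodes found in all 8 populations held 91.1% ± 2.36 of monocyte, 92.5% ± 1.20 of neutrophil and 92.9% ± 1.38 of M1 macrophage reads, but 28.2% ± 8.62 of Ccr2lo reads (SD, n = 3 each). In 100 regroupings that mixed the mice, 0.945% of barcodes on average, and at most 1.31%, were found in all 8 populations, a low share that follows from mice having few barcodes in common. Barcodes in tissue macrophages only made up 46.2% on average in the regroupings, from 34.8% to 59.2%, so that the share within mice lay below each of them. This too follows from mice having few barcodes in common, since regrouping parts macrophages from the blood of their own mouse. Barcodes rare in blood may have been missed there, since the numbers of sorted cells are not known. The shares depended on the threshold for presence. With 0.001% of reads, 26.1% of barcodes were in all 8 populations and 23.5% in tissue only, and with 0.1% these were 4.88% and 50.4%. The 5 leading barcodes of each mouse, 15 in all, reached between 0.00867% and 0.0622% in samples of the other mice, so that the 0.01% taken as presence is near the background that an abundant barcode leaves in other samples.

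**Figure D4:**
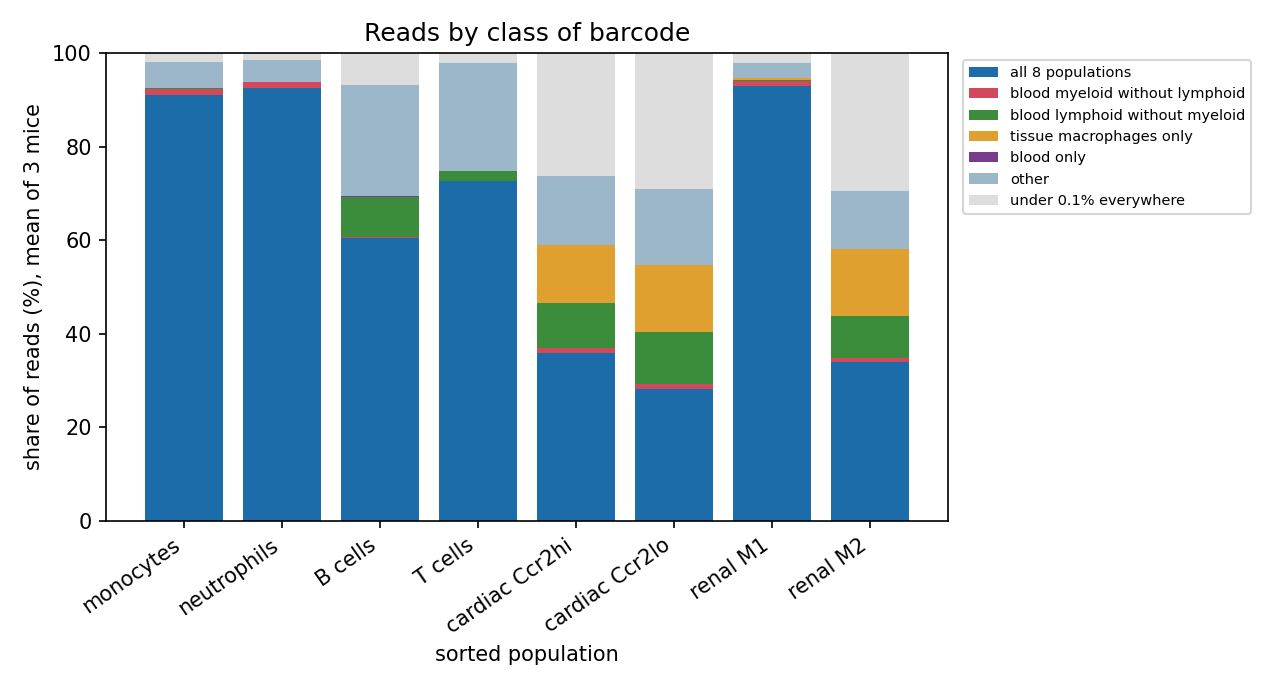
Share of reads (%, mean of 3 mice) of each population in barcodes of each class, with barcodes below 0.1% in all populations of the mouse in light grey. Barcodes found in all 8 populations hold 91.1% of monocyte, 92.5% of neutrophil and 92.9% of renal M1 macrophage reads, and barcodes found only in tissue macrophages hold 12.3% of Ccr2hi, 14.2% of Ccr2lo and 14.4% of M2 reads.

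Blood barcodes were mostly uneven between the lineages. Of the barcodes with a mean of at least 0.1% over the blood populations, 123, 100 and 82 in the 3 mice, 62.1% ± 2.16 were over 4-fold higher in lymphoid cells and 19.5% ± 4.15 over 4-fold higher in myeloid cells (SD, n = 3). Folds compared the mean share of each lineage with 0.01% added, so a barcode high in T cells alone counted as lymphoid. The 10 most abundant barcodes held 67.8% of monocyte and 70.7% of neutrophil reads, against 40.9% of B and 51.99% of T cell reads. This leaves other barcodes a smaller share in myeloid cells, so the counts partly restate that difference. In mouse 1 the most myeloid barcode, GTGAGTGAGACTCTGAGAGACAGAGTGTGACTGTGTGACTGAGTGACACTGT, held 1.04% of monocyte and 1.30% of neutrophil reads but 0.0147% of B cell and 0.0106% of T cell reads. The most lymphoid, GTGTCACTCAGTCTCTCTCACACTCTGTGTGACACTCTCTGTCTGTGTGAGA, held 1.05% of T cell and 0.0125% of monocyte reads. In mouse 2 the most myeloid was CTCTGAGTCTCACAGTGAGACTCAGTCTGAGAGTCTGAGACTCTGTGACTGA, with 11.6% of monocyte and 0.191% of B cell reads. The most lymphoid there, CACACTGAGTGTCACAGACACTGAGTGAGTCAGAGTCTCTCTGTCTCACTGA, had 1.58% of T cell and 0.000383% of monocyte reads. In mouse 3 they were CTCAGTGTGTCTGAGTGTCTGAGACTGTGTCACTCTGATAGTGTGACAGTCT, with 8.74% of monocyte and 0.0588% of T cell reads, and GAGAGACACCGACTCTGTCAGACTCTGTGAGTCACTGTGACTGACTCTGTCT, with 1.47% of T cell and 0.0233% of monocyte reads. Each of the 3 most lymphoid barcodes was higher in T cells than in B cells.

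The barcodes with the highest mean share in a mouse were found in all of its populations, at levels that differed many-fold between them. In mouse 1 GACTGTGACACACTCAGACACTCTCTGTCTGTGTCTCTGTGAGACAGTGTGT led, with 9.57% of monocyte, 10.7% of neutrophil and 10.5% of M1 macrophage reads but 0.702% of B cell and 0.594% of Ccr2lo reads. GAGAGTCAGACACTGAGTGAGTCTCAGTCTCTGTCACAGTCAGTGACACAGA and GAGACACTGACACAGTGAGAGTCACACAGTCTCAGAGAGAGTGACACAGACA followed, with 8.96% and 8.11% of monocyte, 4.30% and 4.79% of B cell, and 0.362% and 0.403% of T cell reads. The next was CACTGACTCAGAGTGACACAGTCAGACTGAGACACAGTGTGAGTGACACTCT, with 8.54% of monocyte reads. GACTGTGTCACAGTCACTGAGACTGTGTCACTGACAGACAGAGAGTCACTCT, the fifth, was higher in B cells (8.41%) and T cells (6.32%) than in monocytes (3.59%).

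In mouse 2 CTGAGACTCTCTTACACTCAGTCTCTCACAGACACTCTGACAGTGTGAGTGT stood apart by its even level, from 4.31% of Ccr2lo to 10.4% of M1 macrophage reads, with 5.60% of B cell and 9.51% of T cell reads. It was the most abundant barcode of Ccr2hi (6.05%), Ccr2lo and M2 macrophages (7.79%) of that mouse. The most myeloid barcode named above was the next, with 14.0% of M1 (Wilson 95% interval 13.9955% to 14.0334%) and 3.04% of Ccr2lo reads. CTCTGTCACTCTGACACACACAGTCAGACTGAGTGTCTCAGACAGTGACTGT, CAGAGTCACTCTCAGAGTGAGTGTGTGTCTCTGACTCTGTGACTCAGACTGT and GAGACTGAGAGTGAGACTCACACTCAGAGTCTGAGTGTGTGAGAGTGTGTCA had 10.6%, 7.19% and 6.42% of monocyte reads and 2.30%, 2.19% and 1.89% of Ccr2lo reads.

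In mouse 3 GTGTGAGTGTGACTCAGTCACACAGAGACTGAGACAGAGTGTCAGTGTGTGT held 18.0% of monocyte and 20.6% of M1 macrophage reads (Wilson 95% interval 20.5733% to 20.6178%) but 4.06% of M2 and 0.195% of T cell reads. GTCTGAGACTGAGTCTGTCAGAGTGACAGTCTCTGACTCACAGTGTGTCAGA had 9.65% of monocyte and 8.25% of B cell reads. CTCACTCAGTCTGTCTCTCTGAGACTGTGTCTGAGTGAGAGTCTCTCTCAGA had 13.8% of monocyte and 0.0845% of T cell reads. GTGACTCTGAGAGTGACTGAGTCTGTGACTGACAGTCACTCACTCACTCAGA had 8.56% of monocyte and 5.79% of T cell reads, and the most myeloid barcode of that mouse was the fifth.

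Single barcodes of the paired subsets were compared within each mouse. Of the barcodes at 0.1% or more in Ccr2hi or Ccr2lo macrophages, 247 ± 39.4 per mouse, 99.5% ± 0.145 lay within 4-fold of each other in the 2 subsets (SD, n = 3). Between M1 and M2 macrophages 11.96% ± 4.56 of 200 ± 7.64 barcodes did, and 158 ± 14.4 were over 4-fold higher in M2 macrophages (SD, n = 3 each). Between monocytes and M1 macrophages 88.0% ± 15.6 of 56 ± 12.5 barcodes lay within 4-fold (SD, n = 3), with only 70% in mouse 1, where 20 of 70 were over 4-fold higher in monocytes. Between neutrophils and M1 macrophages 98.7% ± 1.12 of 48.7 ± 5.13 barcodes lay within 4-fold (SD, n = 3). Ccr2lo and M2 macrophages, of different organs, had 91.6% ± 1.21 within 4-fold (SD, n = 3), and B and T cells 19.3% ± 7.33.

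The main tests across mice used, through their filter, only barcodes that occurred in several mice. Most of these were at trace level in all but 1 mouse or in every mouse. Only 291 barcodes reached 0.01% in 2 or 3 mice. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjusted p under 0.05, 0 of 1621 barcodes differed between Ccr2hi and Ccr2lo macrophages (0 at unadjusted p under 0.05, 0 with DESeq2). Between M1 and M2 macrophages 0 of 1086 differed (8 unadjusted, 107 lower in M1 with DESeq2), and between B and T cells 0 of 1049 (63 unadjusted, 18 with DESeq2). Cardiac and renal macrophages differed in 0 of 2384 (0 unadjusted, 0 with DESeq2). With the mouse as a block, edgeR also called 0 in each of these comparisons, with 23, 30, 14 and 43 at unadjusted p under 0.05, in this order. For tissue macrophages against monocytes the count was 0 of 2069 (72 unadjusted, 201 with DESeq2), and 1 with the mouse as a block. That barcode was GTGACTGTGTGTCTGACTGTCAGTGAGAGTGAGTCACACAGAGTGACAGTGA, log2 fold change 8.87, adjusted p = 0.0371 in edgeR, at most 0.00141% of any sample.

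Between monocytes and neutrophils 1 of 724 barcodes was called by edgeR, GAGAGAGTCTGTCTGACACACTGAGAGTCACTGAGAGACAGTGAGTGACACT, lower in monocytes (log2 fold change -3.62, adjusted p = 0.00747). It was lost with the mouse as a block and in each test without 1 mouse (0 called). Between blood myeloid and lymphoid cells, summed per mouse, edgeR called 8 of 1487 barcodes, 2 higher and 6 lower in myeloid cells, and 0 with the mouse as a block or without any 1 mouse. The higher were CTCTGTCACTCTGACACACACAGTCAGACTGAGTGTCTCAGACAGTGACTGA (2.83) and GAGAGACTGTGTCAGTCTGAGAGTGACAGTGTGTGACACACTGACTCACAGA (1.51), by log2 fold change. The lower were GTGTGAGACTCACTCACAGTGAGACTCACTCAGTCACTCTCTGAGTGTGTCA (-2.95), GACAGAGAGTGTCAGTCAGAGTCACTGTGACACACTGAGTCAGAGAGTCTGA (-2.56), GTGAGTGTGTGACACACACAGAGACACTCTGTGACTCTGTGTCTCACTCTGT (-2.48), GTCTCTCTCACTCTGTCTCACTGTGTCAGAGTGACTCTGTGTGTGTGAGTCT (-2.44), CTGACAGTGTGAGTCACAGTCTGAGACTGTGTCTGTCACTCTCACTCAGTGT (-2.29) and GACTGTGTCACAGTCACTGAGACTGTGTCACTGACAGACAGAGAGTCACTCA (-2.04). Their adjusted p in edgeR lay between 0.00733 and 0.0494, and none reached more than 0.0821% of any sample. Of the 8, 3 had a neighbour differing by 1 base that was over 100 times as abundant.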

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

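Except for the tests of unsorted blood and of a library deposited under several names, the tests in this part were chosen after the result was seen. Renal M1 macrophages lay nearer to blood myeloid cells. By overlap, cardiac Ccr2lo and renal M2 macrophages lay slightly nearer to the mean of blood lymphoid cells, through B cells and not T cells. Overlap also depends on how evenly reads are spread over barcodes. The effective number was 111 in B cells, 50.2 in T cells, 32.1 in monocytes and 27.2 in neutrophils. A higher overlap with B cells therefore need not mean closer descent. M2 macrophages overlapped by 0.402 with B cells but by 0.263 with T cells, below monocytes (0.320) and neutrophils (0.295). Ccr2lo macrophages overlapped by 0.392 with B cells and 0.238 with T cells, against 0.246 with monocytes and 0.221 with neutrophils. The overlap with blood myeloid minus that with blood lymphoid cells was above 0 in all 3 mice for M1 macrophages and below 0 in all 3 for cardiac Ccr2lo and renal M2 macrophages, while cardiac Ccr2hi macrophages had both signs (0.0356 in mouse 2, below 0 in mice 1 and 3). The M1 mean exceeded that of Ccr2lo macrophages by 0.685 and that of M2 macrophages by 0.629 (exact permutation p = 0.1 each, the smallest possible with 3 against 3). These results stood out because every sample of one subset lay on the opposite side of 0 from every sample of the other.

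The pattern behind both is that M1 macrophages carried the repertoire of blood myeloid cells. Blood left in the kidney and not sorted would bring B cells, but barcodes that B cells held at 0.1% or more and myeloid cells lacked took at most 0.121% of M1 reads in any mouse, against 6.88% ± 1.94 of B cell reads (SD, n = 3). General carry-over of reads between libraries would bring barcodes of other mice. Those at least 100 times as abundant in another mouse took at most 0.637% of M1 reads. Carry-over confined to the libraries of the same mouse would not show in this value and was not tested. M1 and monocyte files were not one library, since the chi-square over its degrees of freedom was at least 138. Blood monocytes or neutrophils inside the M1 sort and recent descent of M1 macrophages from monocytes cannot be told apart. Each predicts nearly the same barcodes, and at most 2.72% of M1 reads lay in barcodes under 0.001% in monocytes and neutrophils. In mouse 1 M1 macrophages overlapped more with neutrophils (0.888) than with monocytes (0.856). In mice 2 and 3 they overlapped more with monocytes (0.918 and 0.912) than with neutrophils (0.905 and 0.871).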

How the results depend on the processing

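Leaving out renal M1 macrophages, with or without pairing, restricting to the alternating pattern and the tests on other splits of the samples were chosen after the results were seen. Of 135 alternative values of the measures and similarities, 119 kept their direction and side of the threshold. The number and effective number of barcodes, the shares of the most abundant barcodes, blood against tissue, same against different mice and class within mice did so in every alternative run. Ccr2hi against Ccr2lo and M1 against M2 kept their direction, but 3 samples against 3 cannot pass the threshold. With the inverse Simpson index, cardiac against renal macrophages passed the threshold (4.02-fold, exact permutation p = 0.0498). Without renal M1 macrophages that ratio turned to 0.978, the similarity to monocytes lost its call (eta squared 0.174, permutation p = 0.554, or 0.167 with the mouse as a block) and the myeloid minus lymphoid overlap turned to -0.0540, which the removal of that subset itself accounts for. The latter difference was 0.139 and no longer called with the Morisita-Horn index, -0.0111 with the Jaccard index and 0.111 and not called with barcodes of the alternating pattern only. Its call was kept with Spearman correlation (0.150, permutation p = 0.00968). Eta squared of the similarity to monocytes was 0.0624 with Spearman correlation. The cause was not tested for these. Leaving out 1 mouse gave 0.380 to 0.450 for myeloid over lymphoid diversity, 0.931 to 0.989 for the similarity to monocytes and 0.0979 to 0.122 for the myeloid minus lymphoid overlap; fewer mice allow fewer permutations.

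Of 42 alternative shares of barcode classes, 32 moved by less than 1 SD, and the others changed with the threshold for presence. At 0.001% of reads, 26.1% were in all 8 populations, 1.22% myeloid without lymphoid, 23.5% tissue only and 28.8% other. At 0.1%, 4.88% were in all 8, 5.05% myeloid without lymphoid, 33.4% lymphoid without myeloid and 50.4% tissue only. A further 0.544% were in both blood lineages without tissue, and 5.64% were other.

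Of 66 alternative counts of called barcodes, 45 stayed within 1.5 times. Most of these set 0 against 0, which says little, since the main test recovered 0% of simulated changes at the level of each mouse. The count for myeloid against lymphoid cells moved in every alternative, and that for monocytes against neutrophils stayed only without TMM and after merging. DESeq2 called 107 for M1 against M2, 18 for B against T cells, 201 for tissue macrophages against monocytes, 15 for myeloid against lymphoid cells and 0 for monocytes against neutrophils. With the mouse as a replicate block the counts were 0 for monocytes against neutrophils, 0 for myeloid against lymphoid and 1 for tissue against monocytes, and changed no other count by over 1.5 times. Permutation within mice changed no call among the 10 measures it was run for; the overlap within and between mice, by class and with myeloid against lymphoid cells had no such alternative, since their tests already use the mouse. For myeloid against lymphoid cells, 17 were called without TMM, 4 after merging, 3 with samples entered singly, and 0 without a filter or with at least 10 reads in every sample; these filters also left 0 for monocytes against neutrophils. Without 1 mouse both comparisons ranged from 0 to 0. The cause was not tested.

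Each comparison of 3 against 3 has 10 splits of its 6 samples, too few for a share under 0.05. Where the real split called 0, all 10 splits call as many by construction, which tests nothing: Ccr2hi against Ccr2lo, M1 against M2, cardiac against renal and tissue against monocytes (highest other 0), and B against T cells (highest other 13). As many as in the real split were called in 10 of 10 splits for myeloid against lymphoid (8, highest other 31) and in 4 of 10 for monocytes against neutrophils (1, highest other 3). For myeloid against lymphoid, the 31 came from a split that parts 1 of the pairs, and the highest among the other splits that part every pair was 14. A count several times the real one points to a structure of the samples, whose cause was not tested. Differences in depth between samples did not account for the calls of the measures and similarities, since thinning to the shallowest sample changed none of them. Thinning cannot show whether each sample held enough cells or reads. The barcode classes and the tests of single barcodes were not run on thinned counts.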

Other observations

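The tests of sequencing depth, of sequencing errors and of how many heart reads recur in kidney barcodes were planned before their results were seen, and the other tests in this part were chosen after. Cardiac and renal M2 macrophages shared barcodes that the blood samples lacked, which here means under 0.001% of reads in each. The numbers of sorted blood cells are not known, so barcodes rare in blood may have been missed there. Barcodes under 0.001% in all 4 blood populations of the mouse held 26.7% ± 5.35 of Ccr2hi, 30.2% ± 4.16 of Ccr2lo and 32.2% ± 5.91 of M2 reads, but 1.35% ± 0.569 of M1 reads (SD, n = 3 each). Of these Ccr2lo reads 76.2% ± 2.82 (SD, n = 3), and at least 73.8% in each mouse, lay in barcodes that renal M2 macrophages of the mouse held at 0.01% or more. Only 4.14% ± 0.786 lay in barcodes of M2 macrophages of another mouse (SD, n = 3). A bound of 50% was set beforehand against random draws in each organ, but recurrence alone cannot exclude them, since the size of the pool that the organs drew from was not measured. Levels were compared instead, over the 538, 365 and 479 barcodes of the 3 mice that Ccr2lo and M2 macrophages both held and blood lacked. The median absolute log2 ratio of Ccr2lo to M2, after centring, was 0.73, 0.69 and 0.67, against 1.06, 1.07 and 1.08 on average with levels shuffled among these barcodes. It was at most 0.795 of the lowest of 1000 shuffled medians, which argues against levels set by chance in each organ. Random draws in proportion to the size of clones common to both organs cannot be told apart from other shared sources.

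Cardiac Ccr2hi, cardiac Ccr2lo and renal M2 macrophages had 13.4-fold the effective number of barcodes of the other populations, a grouping of populations made after the values were seen and used only to follow the ratio, not to test it. The ratio was 13.3 after thinning to one depth, 13.4 after merging 1-mismatch neighbours and 13.6 without barcodes of other mice, so these do not account for it. Few cells drawn from a repertoire as wide as that of cardiac and M2 macrophages would make separate sorts of one mouse differ. Monocytes, neutrophils and M1 macrophages instead overlapped by at least 0.856, in a test widened to all 3 populations after values had been seen. Overlap weights barcodes by reads, and the 10 most abundant held 67.8% of monocyte, 70.7% of neutrophil and 72.5% of M1 reads. The test therefore says little on rare barcodes, and the numbers of sorted cells are not known. Few sorted cells as a cause of low barcode counts in these 3 populations cannot be excluded. Cell numbers of B and T cells were not tested. A biological difference between the populations stays open and was not tested.

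Of 18 barcodes at 0.005% or more in all 24 samples, 15 reached at least 4.88% in some sample of 1 mouse, and 3 did not: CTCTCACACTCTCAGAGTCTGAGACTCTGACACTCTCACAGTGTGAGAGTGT, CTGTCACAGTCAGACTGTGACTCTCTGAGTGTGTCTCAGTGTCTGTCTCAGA and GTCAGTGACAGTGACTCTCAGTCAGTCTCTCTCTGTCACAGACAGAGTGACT. These averaged 0.165% in monocytes, neutrophils, cardiac and M1 macrophages, 0.0277% in B and T cells and 0.0462% in M2 macrophages, and their mean level differed between populations (eta squared 0.922, permutation p = 1e-05, the smallest possible). Carry-over among these 24 libraries would need one where they are abundant, but their highest share in any was 0.360%; libraries outside this set were not analysed here. A constant amount of foreign template in each PCR would keep their ratios fixed; instead each ratio of 2 of them varied by 5.27-fold to 5.95-fold, above the 2-fold taken to fit and below the 20-fold taken to exclude it. These bounds were set once the ratios were known and after a correlation had decided nothing, and the number of template molecules is not known, so it cannot be told apart from founder cells that carry these barcodes in every mouse.

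T cells of mouse 3 were led by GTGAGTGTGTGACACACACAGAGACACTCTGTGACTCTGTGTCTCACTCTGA (15.3%), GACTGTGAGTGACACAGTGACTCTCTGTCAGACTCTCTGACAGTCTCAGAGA (14.9%) and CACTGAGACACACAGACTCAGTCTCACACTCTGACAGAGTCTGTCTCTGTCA (14.8%). The log2 ratio of the first to the last had an SD of 0.0571 over the 8 populations, while that of the first to the other was 2.19. A hypothesis is that some founder cells carried several barcodes. Among barcodes present in all 8 populations, 23 of 4216 pairs of one mouse had an SD under 0.3, against 4 of 8030 pairs of barcodes from different mice with each mouse's mean profile subtracted, an 11.0-fold excess. The subtraction was added after the first form of this test, without it, had given 2 of 8030 pairs and a 21.9-fold excess, and the 10-fold bound set for that form is passed only narrowly. Such pairs may make the number of barcodes larger than the number of founder cells.

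Ccr2hi macrophages overlapped more with monocytes than Ccr2lo macrophages did in 3 of 3 mice. A candidate explanation is a monocyte-like part added to a repertoire shared with Ccr2lo macrophages. In a non-negative fit of Ccr2hi shares by Ccr2lo and monocyte shares, monocytes had weights of 0.0465, 0.140 and 0.0469 in the 3 mice, at least 0.0465, and in the fit of Ccr2lo by Ccr2hi and monocyte shares they had a weight of 0 in each. The fit was chosen after the higher overlap had been seen and largely restates it. The overlap of Ccr2hi also exceeded that of Ccr2lo macrophages in 3 of 3 mice with neutrophils (by 0.0622 ± 0.0229), B cells (by 0.0370 ± 0.0271) and T cells (by 0.0350 ± 0.0190; SD, n = 3 each), and in mouse 3 by more with B cells (0.0681) than with monocytes (0.0589), so a part particular to monocytes stays open.

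The T cell sample of mouse 2 had the largest share of reads in barcodes of other mice, 1.44%, against a median of 0.482% over the 24 samples.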
